A study of Rattus norvegicus with 24 samples.

How the data were processed

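Gene expression was measured in primary rat hepatocytes cultured either on a single layer of collagen gel, called monolayer here, or between 2 layers of collagen gel, called sandwich here. Per the labels, the second layer was laid on after the cells had been seeded, RNA was taken at days 1, 2, 3 and 8 after that deposition, and each culture and day had 3 replicates, which makes 8 groups and 24 Affymetrix arrays. Nothing in the labels says whether the replicates came from separate animals or separate cultures, so the p-values may describe technical spread as much as spread between cultures. All 24 arrays were used.

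The deposited values are log2 probe set summaries from biotin-labelled cRNA, normalized between arrays by the authors. The submitters' processing notes name RMA, a summarization and normalization method for Affymetrix arrays, and limma, with neither a role nor a version. The values were taken as deposited. They ran from 2.61 to 15.07, no value was missing, the array medians lay between 5.57 and 5.67, and no pair of arrays was identical. Pearson correlations across probe sets were 0.993 to 0.997 between arrays of the same group and 0.958 to 0.995 between arrays of different groups; probe sets are not independent replicates, so these describe similarity only. The table holds 31099 probe sets, of which 57 control probe sets were left out and 31042 were tested. Of those, 20826 carried exactly 1 gene symbol, 436 several and 9780 none. Symbols were updated through the gene identifiers of the platform annotation to those of the reference annotation. A gene was read by the probe set of its symbol with the highest mean over all 24 arrays, which gave 14217 genes, 4525 of them with several probe sets. The table holds no detection calls, and the number of arrays limits the precision. Where the lower group mean of a gene lies below the median of all probe sets, 5.62, its background is unknown, and the difference is given on the log2 scale without a fold.

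Differences were tested with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 24 arrays, so that all groups shared 1 estimate of the spread per probe set, and p-values were adjusted by the Benjamini-Hochberg method over the 31042 probe sets within each comparison. A probe set was called at an adjusted p under 0.05, two-sided. The comparisons were sandwich against monolayer at each day and over the mean of the 4 days, days 2, 3 and 8 against day 1 in each culture, the culture by day interaction (a moderated F test), and the difference between the cultures in the change from day 1 to day 8. Differences are given on the log2 scale as sandwich minus monolayer, or later day minus day 1, with the standard error (SE) of the model.

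The genes named follow a rule fixed before the data were examined. For each culture comparison at a day and for day 8 against day 1 in each culture, they are the 10 largest rises and the 10 largest falls among called genes whose 3 arrays of one group all lie above the 3 of the other. For the difference between the changes they are the 8 largest in each direction. For each gene list they are the 4 measured members with the smallest adjusted p. Named whatever their values are Alb, Ttr, Hnf4a, Cebpa, Cyp2e1, Cyp7a1, Cps1, Tat, Slc10a1, Abcb11, Afp, Krt19, Vim, Acta2, Col1a1, Ccnd1 and Mki67. The beta-actin gene Actb was also on that list, and is not analysed here because its probe set carries several symbols. Genes named outside the rule are said to have been chosen after their values were seen.

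The 34 gene lists were also fixed before the data were examined, 28 of hepatocyte functions and cell processes and 6 of markers of other cell types a liver cell preparation could hold. They were plasma proteins, coagulation and complement, acute phase, phase I and phase II drug metabolism, hepatic transporters, bile acid synthesis, urea cycle and amino acid catabolism, gluconeogenesis with fructose and glycogen metabolism, glycolysis, fatty acid oxidation, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, liver transcription factors, actin cytoskeleton and contractility, mesenchymal transition, collagen and extracellular matrix, matrix proteases, integrins and focal adhesion, junctions and polarity, cell cycle, fetal and progenitor markers, inflammation, oxidative stress, endoplasmic reticulum stress, heat shock, immediate early genes, and markers of stellate cells, macrophages, endothelial cells, cholangiocytes, lymphocytes, and neutrophils with erythroid cells. Some genes sit on several lists. Each list was compared with the other genes by limma's camera, with a preset correlation between genes of 0.01, on 1 probe set per gene, and the p-values were adjusted together over 34 lists and 8 comparisons. Each was also tested with a correlation estimated from the data by camera, which is stricter for lists whose genes move together, and with fry, which tests a list by itself. Members of a list are counted as called over all probe sets. For some lists the number called when p-values were adjusted over the list alone is given beside that count.

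The pipeline was tested on simulated data, drawn with the mean and residual spread of each probe set of the real table, with changes added to some of the 31042 probe sets in the day 8 comparison. It called 42 of 67 changes of 0.5 on the log2 scale, 64 of 67 changes of 1.0 and 66 of 66 changes of 2.0, and 17 of the unchanged probe sets. No other probe sets were changed, whereas 27.5% were called in the real day 8 comparison. The adjustment of p-values depends on that share, so these rates need not carry over to the real comparisons. Shifting the genes of 2 lists by 0.3 led to calls for both and for 0 of the other lists. Each probe set was drawn independently, so the simulated genes were not correlated. In the real data the estimated correlation was above 0.01 in 33 of 34 lists. The 0 false list calls therefore do not carry over to the real lists.

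Alternatives fixed before the data were examined were quantile normalization, centring each array on its median, fitting only the arrays of the groups compared, array weights, a variance prior with a trend and robust estimation, the replicate number as a block, 1 probe set per gene, the mean of all probe sets of a gene, leaving out the 40% of probe sets with the lowest mean, leaving out probe sets whose identifiers mark possible cross-hybridization, an adjusted p under 0.01, a change of at least 2-fold, and leaving out each array of the groups compared in turn. Alternatives chosen after the data were seen were the 3' minus 5' difference of the beta-actin control probe sets as a covariate, the interquartile range of each array as a covariate, and leaving out all 8 arrays numbered 1. RNA quality measures were compared between the cultures by permuting the culture labels within each day, with all 160000 assignments, and the p-values of the 6 measures were adjusted together. Counts were also recomputed for other assignments of the arrays to the groups, all 10 splits of 3 against 3 or 100 drawn with a fixed seed of 20. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.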

Results

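The series asked how gene expression in primary rat hepatocytes differs between culture on 1 layer of collagen gel (monolayer) and culture between 2 layers (sandwich). In the labels, monolayer cultures serve as an unstable control and sandwich cultures as a stable one. Each culture was profiled on 3 arrays at each of days 1, 2, 3 and 8 after the second layer was laid on, 24 arrays in all. Values are log2 probe set levels, and the number of arrays, 3 per group, limits their precision. In a principal component analysis the first component held 42.0% of the variance and the second 20.1%. Along the first, monolayer arrays moved from between -24.8 and -21.5 at day 1 to between 62.6 and 65.6 at day 8. Sandwich arrays moved from between -33.0 and -31.1 to between 5.39 and 8.18. Along the second component it was the sandwich arrays that moved further, from between -20.2 and -15.9 at day 1 to between 40.9 and 43.8 at day 8. Monolayer arrays moved there from between -27.7 and -22.9 to between -12.6 and -7.50.

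The cultures drew apart from day to day, in liver metabolism on the sandwich side and in cytoskeletal, mesenchymal and cell cycle genes on the monolayer side. Of 31042 probe sets, 552 differed between sandwich and monolayer at day 1, 1809 at day 2, 5133 at day 3 and 8543 at day 8. Of these, 178, 581, 2390 and 3695 were higher in sandwich and 374, 1228, 2743 and 4848 were lower. Differences of at least 2-fold numbered 54, 208, 727 and 1368. Counted as genes, 366, 1233, 3229 and 5158 were called. Of all genes, called or not, 21.1%, 24.4%, 37.0% and 45.9% had all 3 arrays of one culture above the 3 of the other, against 10% by chance. Of the 552 probe sets called at day 1, 421 were also called at day 8, 351 in the same direction and 70 in the opposite one. Independent lists would share about 79.6 in the same direction.

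RNA quality measures also differed between the cultures. The 3' minus 5' difference of the beta-actin control probe sets was 0.82 ± 0.04 in monolayer and 0.99 ± 0.11 in sandwich (log2, SD, n = 12 each, exact permutation p = 1.25e-04, adjusted p = 3.75e-04 over 6 measures). Its group means ran from 0.79 to 0.86 in monolayer and from 0.94 to 1.03 in sandwich, so it stood beside every culture difference given here. The 3' probe set of beta-actin itself was 13.63 ± 0.23 in monolayer and 13.10 ± 0.11 in sandwich (exact permutation p = 1.25e-05, adjusted p = 7.50e-05), in the direction of the actin cytoskeleton list. For GAPDH the 3' minus 5' difference was 0.27 ± 0.07 and 0.32 ± 0.10 (exact permutation p = 0.137, adjusted p = 0.205).

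**Figure D1:**
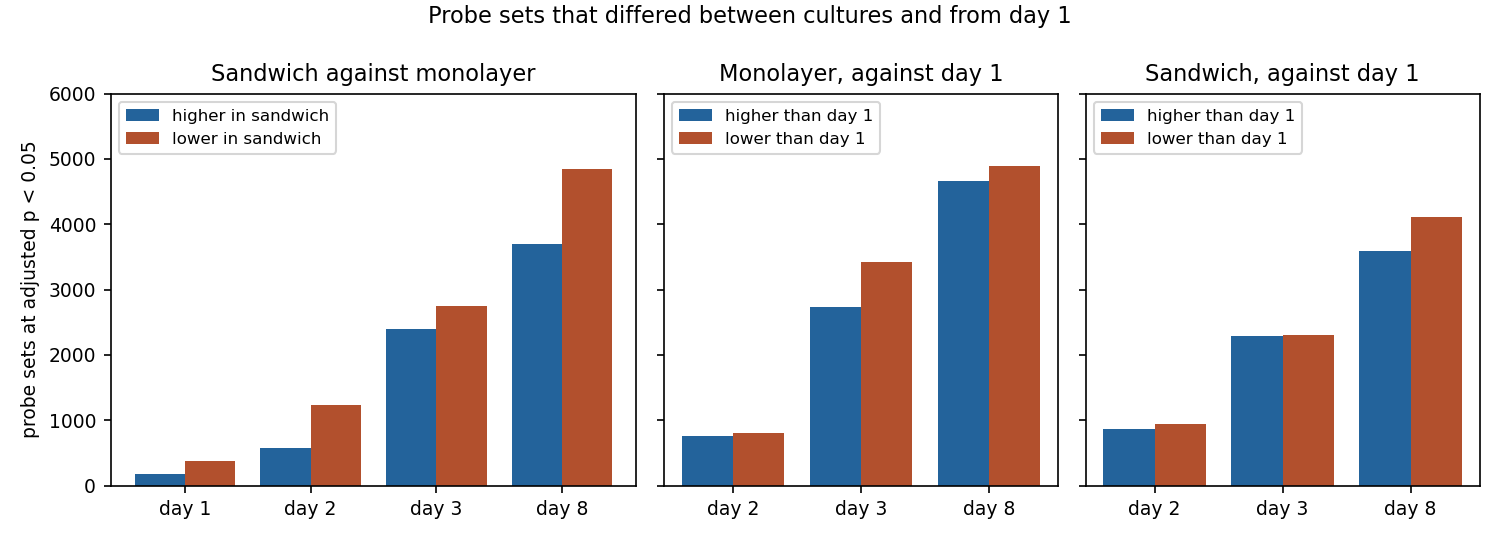
Number of probe sets at an adjusted p under 0.05 (vertical axes) for sandwich against monolayer at each day and for days 2, 3 and 8 against day 1 in each culture, with bars for higher and lower values. Culture differences grew from 552 probe sets at day 1 to 8543 at day 8.

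At day 1, sandwich cells held more transcripts of heat shock proteins, endoplasmic reticulum chaperones and cholesterol synthesis, and fewer of the actin cytoskeleton and of inflammatory mediators. The largest difference was Hspa1a, an inducible heat shock protein of the Hsp70 family. It stood at 11.72 ± 0.12 against 8.18 ± 0.13 on the log2 scale in sandwich and monolayer (mean ± SD, n = 3 each), 11.6-fold higher (adjusted p = 4.99e-15). The small heat shock protein Hspb1 was higher by 1.42 ± 0.12 (log2 difference ± SE). Among the 10 largest rises were also Pdk4, which restrains pyruvate oxidation, at 1.56 ± 0.18, the interferon-induced Rsad2 at 1.29 ± 0.22 and the immediate early gene Egr1 at 1.00 ± 0.12. Csad, Zfand2a, Phlda1, C4bpb and Idi1 made up the rest, at 1.29, 1.10, 1.07, 0.98 and 0.91. The 10 largest falls included Sox4, a transcription factor of progenitor cells, at -2.12 ± 0.18, the calcium-binding protein S100a6 at -1.68 ± 0.10 and Tagln, an actin-binding protein of contractile cells, at -1.48 ± 0.25. Acta1, Steap4, Prss23, Filip1l, Tsx, Il1rl1 and Cxcl3 lay between -1.99 and -1.28. The call of Phlda1 (adjusted p = 0.0473) ended without monolayer replicate 2 (adjusted p = 0.239) or 3 (0.175) or sandwich replicate 1 (0.227) or 3 (0.132) of that day.

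Endoplasmic reticulum stress genes moved together at day 1. Of 27 measured, 12 were higher in sandwich, 0 lower and 15 did not pass, and 19 were higher when adjusted over the list alone (median 0.48, adjusted p = 1.73e-24, and adjusted p = 0.0036 with an estimated correlation). Examples were Herpud1 at 0.76 ± 0.09 and the chaperones Pdia4 at 0.70 ± 0.10 and Hsp90b1 at 0.55 ± 0.08. Heat shock had 3 higher and 0 lower of 13, and 4 higher adjusted over the list alone (adjusted p = 5.60e-06, and 0.0468 with an estimated correlation). Immediate early genes had 3 higher and 0 lower of 23, and 9 and 1 adjusted over the list alone (adjusted p = 5.83e-08, and 0.0122 with an estimated correlation). Cholesterol synthesis had 3 higher and 0 lower of 21, and 12 higher adjusted over the list alone (adjusted p = 1.40e-11, and 0.0492 with an estimated correlation), with Idi1 at 0.91 ± 0.13 and Msmo1 at 0.61 ± 0.11. Actin cytoskeleton genes were lower in 10 of 32 and higher in 0, with 14 lower adjusted over the list alone (adjusted p = 3.08e-15, and 0.0048 with an estimated correlation). They included the actin cross-linkers Flna at -0.87 ± 0.12 and Actn1 at -1.04 ± 0.15. Mesenchymal transition genes were lower in 10 of 35 and higher in 0, with 12 lower adjusted over the list alone (adjusted p = 8.10e-07, and 0.0145 with an estimated correlation). Inflammation genes were lower in 10 of 30 and higher in 0, with 11 and 1 adjusted over the list alone (adjusted p = 1.35e-06, and 0.0038 with an estimated correlation), among them the chemokines Cxcl10 at -1.04 ± 0.15 and Cxcl2 at -0.76 ± 0.12.

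Of 18 lists called at day 1, the other 11 did not hold with an estimated correlation. Their adjusted p-values with an estimated correlation were 0.229 for plasma proteins, 0.406 for coagulation and complement, 0.26 for acute phase, 0.195 for gluconeogenesis and 0.146 for fatty acid oxidation. They were 0.326 for oxidative phosphorylation, 0.0665 for integrins, 0.23 for junctions, 0.14 for cell cycle, 0.203 for oxidative stress and 0.24 for lymphocyte markers. These p-values, and those of the 7 lists that held, were adjusted over all comparisons together. Adjusted within day 1 alone, only 5 lists were called with an estimated correlation, so some of the 7 calls rest on the joint adjustment. Heat shock and cholesterol synthesis had the largest adjusted p-values of the 7. The day 1 count of 552 fell to 366, 322 and 326 without monolayer replicate 1, 2 and 3, to 339 and 331 without sandwich replicate 1 and 2, and to 465 without sandwich replicate 3. After quantile normalization 257 probe sets were higher and 335 lower, with each array centred on its median 121 and 369, and with the interquartile range of the arrays as a covariate 351 and 348, against 178 and 374. With array weights the count was 933.

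By day 2, genes of lipid synthesis, amino acid breakdown and glucose synthesis stood higher in sandwich cells, and those of contraction, adhesion and cell division lower. Slc10a1, the sodium-dependent bile acid carrier of hepatocytes, stood at 9.19 ± 0.26 against 7.65 ± 0.33 in sandwich and monolayer (mean ± SD, n = 3 each), 2.91-fold higher (adjusted p = 8.78e-07). Idi1, an isoprenoid enzyme of cholesterol synthesis, was 3.02-fold higher (adjusted p = 1.03e-08). Acta1, skeletal alpha-actin, stood at 5.82 ± 0.37 against 9.44 ± 0.21, 12.3-fold lower (adjusted p = 6.62e-09), and Tagln was 9.32-fold lower (adjusted p = 2.68e-09). Sult2a2, Pdk4, Pemt, Hrg, S1pr1, Acss2, Acat2 and Hsd17b7 were the other large rises, from 1.37 to 1.66 on the log2 scale. The other large falls were Sox4 at -3.10 ± 0.18, Car3 at -2.52 ± 0.17, the matricellular protein Ccn2 at -2.18 ± 0.15, and Cxcl3, Cav1, Marcksl1, Serpinb9 and Flrt3, from -2.45 to -2.14.

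Cholesterol synthesis at day 2 was higher in 19 of 21 genes and lower in 0, with 19 higher adjusted over the list alone (median 0.92, adjusted p = 5.97e-35, and 0.0046 with an estimated correlation). Hsd17b7 at 1.37 ± 0.11 and Ebp at 1.02 ± 0.09 were examples. Fatty acid synthesis was higher in 8 of 19 and lower in 0, with 11 higher adjusted over the list alone (adjusted p = 4.51e-13, and 0.0261 with an estimated correlation), and its synthase Fasn stood at 1.18 ± 0.14. Urea cycle and amino acid genes were higher in 20 of 40 and lower in 1, with 26 and 1 adjusted over the list alone (adjusted p = 1.06e-16, and 0.0307 with an estimated correlation), and arginase Arg1 stood at 0.98 ± 0.11. Gluconeogenesis was higher in 7 of 16 and lower in 0, with 9 higher adjusted over the list alone (adjusted p = 5.83e-08, and 0.0182 with an estimated correlation), and its phosphatase Fbp1 stood at 1.04 ± 0.10. Endoplasmic reticulum stress genes were higher in 12 of 27 and bile acid synthesis genes in 2 of 15, with none lower (adjusted p = 0.0102 and 0.0404 with an estimated correlation).

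Among the lists lower in sandwich at day 2, actin cytoskeleton had 22 of 32 lower, and 26 adjusted over the list alone (median -0.49, adjusted p = 3.55e-28, and 0.0012 with an estimated correlation), with Cnn2 at -1.73 ± 0.11. Mesenchymal transition had 14 of 35 lower, integrins and focal adhesion 12 of 36, and cell cycle 19 of 44 (adjusted p = 0.0055, 0.0079 and 0.0059 with an estimated correlation). None of these 4 lists had a member called higher over all probe sets. The G1 cyclin Ccnd1 stood at -1.42 ± 0.16 and the replication helicase subunit Mcm6 at -1.11 ± 0.13. Inflammation had 7 lower and 1 higher of 30 (adjusted p = 0.0239 with an estimated correlation), with the chemokine Ccl2 at -1.80 ± 0.17 and Nfkbiz at 1.08 ± 0.13. The other 13 of 24 called lists had adjusted p-values from 0.0586 to 0.528 with an estimated correlation. With array weights the day 2 count was 3688 instead of 1809, 1578 higher and 2110 lower, and with the interquartile range of the arrays as a covariate 1122 probe sets were higher and 1308 lower.

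At day 3, genes of amino acid, lipid, glucose and drug metabolism and of plasma proteins stood higher in sandwich, and contractile, mesenchymal and cell cycle genes stood higher in monolayer. Acta1 stood at 6.10 ± 1.02 against 11.76 ± 0.21 in sandwich and monolayer (mean ± SD, n = 3 each), 50.6-fold lower in sandwich (adjusted p = 4.49e-13), and Tagln at 6.15 ± 0.72 against 11.29 ± 0.13, 35.3-fold lower (adjusted p = 1.00e-13). Fabp1, the liver fatty acid carrier, was higher in sandwich by 3.03 ± 0.18 on the log2 scale (adjusted p = 5.83e-12) and Slc10a1 was 7.94-fold higher (adjusted p = 2.25e-12). Other large rises were Sult2a2, a sulfotransferase, at 3.06 ± 0.26, the plasma protein Hrg at 2.81 ± 0.14, and Pemt, Ftcd, Clec14a, Apon, Rbp7 and S1pr1, from 2.29 to 2.62. Other large falls were Car3 at -4.41 ± 0.17, the surface glycoprotein Cd24 at -4.15 ± 0.21, the caveola protein Cav1 at -3.98 ± 0.21, and Sox4, Map2, Anxa1, Marcksl1 and Plscr2, from -4.30 to -3.59.

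Urea cycle and amino acid genes at day 3 were higher in 35 of 40 and lower in 0, with 37 higher adjusted over the list alone (median 0.92, adjusted p = 3.58e-29, and 0.0083 with an estimated correlation), such as the transaminases Got1 at 1.68 ± 0.10 and Agxt at 1.32 ± 0.08. Cholesterol synthesis was higher in 19 of 21, fatty acid synthesis in 17 of 19, gluconeogenesis in 10 of 16 and bile acid synthesis in 10 of 15, with none lower. Their adjusted p-values with an estimated correlation were 0.0141, 0.0148, 0.0084 and 0.0112. Plasma proteins had 22 higher and 0 lower of 29, phase I drug metabolism 20 and 2 of 39, and phase II 22 and 3 of 39 (adjusted p = 0.03, 0.0236 and 0.0239 with an estimated correlation). Examples were the apolipoprotein Apoc2 at 1.76 ± 0.12, the cytochrome Cyp3a23-3a1 at 2.26 ± 0.16 and the glutathione transferase Gsta3 at 1.95 ± 0.15. Transporters had 14 higher and 3 lower of 30, fatty acid oxidation 19 and 1 of 34, and oxidative stress 10 and 1 of 23, with catalase Cat at 1.24 ± 0.12 (adjusted p = 0.0288, 0.0385 and 0.0416 with an estimated correlation). Macrophage markers moved in the same direction, with 12 higher and 1 lower of 20 (median 0.49, adjusted p = 1.54e-04, and 0.0435 with an estimated correlation), such as the complement gene C1qc at 0.85 ± 0.13 and the scavenger receptor Cd163 at 0.67 ± 0.11.

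Actin cytoskeleton genes at day 3 were lower in 30 of 32 and higher in 0 (median -0.85, adjusted p = 9.64e-29, and 0.0012 with an estimated correlation), with Flna at -2.62 ± 0.12. The mesenchymal list had 20 lower and 0 higher of 35, integrins 19 and 0 of 36, matrix proteases 9 and 0 of 30, and cell cycle 32 and 0 of 44. Their adjusted p-values with an estimated correlation were 0.0036, 0.0055, 0.0147 and 0.0038. The protease inhibitor Timp1 stood at -1.40 ± 0.09 and the ubiquitin ligase partner Ube2c at -1.14 ± 0.10. Of 23 called lists 17 held, and the other 6 had adjusted p-values from 0.0566 (coagulation and complement, 24 of 29 higher) to 0.255 (collagen and extracellular matrix, 9 of 36 lower) with an estimated correlation.

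At day 8 sandwich cells held more transcript of genes of amino acid, lipid, glucose and drug metabolism, and monolayer cells more of cytoskeletal, mesenchymal and bile duct-type genes. Ugt2b1, a glucuronosyltransferase, stood at 11.66 ± 0.11 against 7.09 ± 0.26 in sandwich and monolayer (mean ± SD, n = 3 each), 23.9-fold higher (adjusted p = 3.33e-18). Cyp17a1, a steroid hydroxylase, was higher by 4.34 ± 0.17 on the log2 scale (adjusted p = 6.80e-16), and Mat1a, the liver form of methionine adenosyltransferase, was 12.5-fold higher (adjusted p = 1.70e-17). Acta1 was 50.5-fold lower in sandwich (adjusted p = 1.42e-13), and Anxa1, an annexin, stood at 7.66 ± 0.25 against 12.21 ± 0.04, 23.5-fold lower (adjusted p = 1.62e-16). Clec14a, Apoa2, G0s2, Pdk4, Ftcd, Slc10a1 and Sult2a2 were the other large rises, from 3.47 to 4.07 on the log2 scale. The other large falls were Car3 at -5.32 ± 0.17, Cd24 at -4.68 ± 0.21, and Plscr2, Sox4, Cpe, Tagln, Map2 and Marcksl1, from -4.29 to -3.76.

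**Figure D2:**
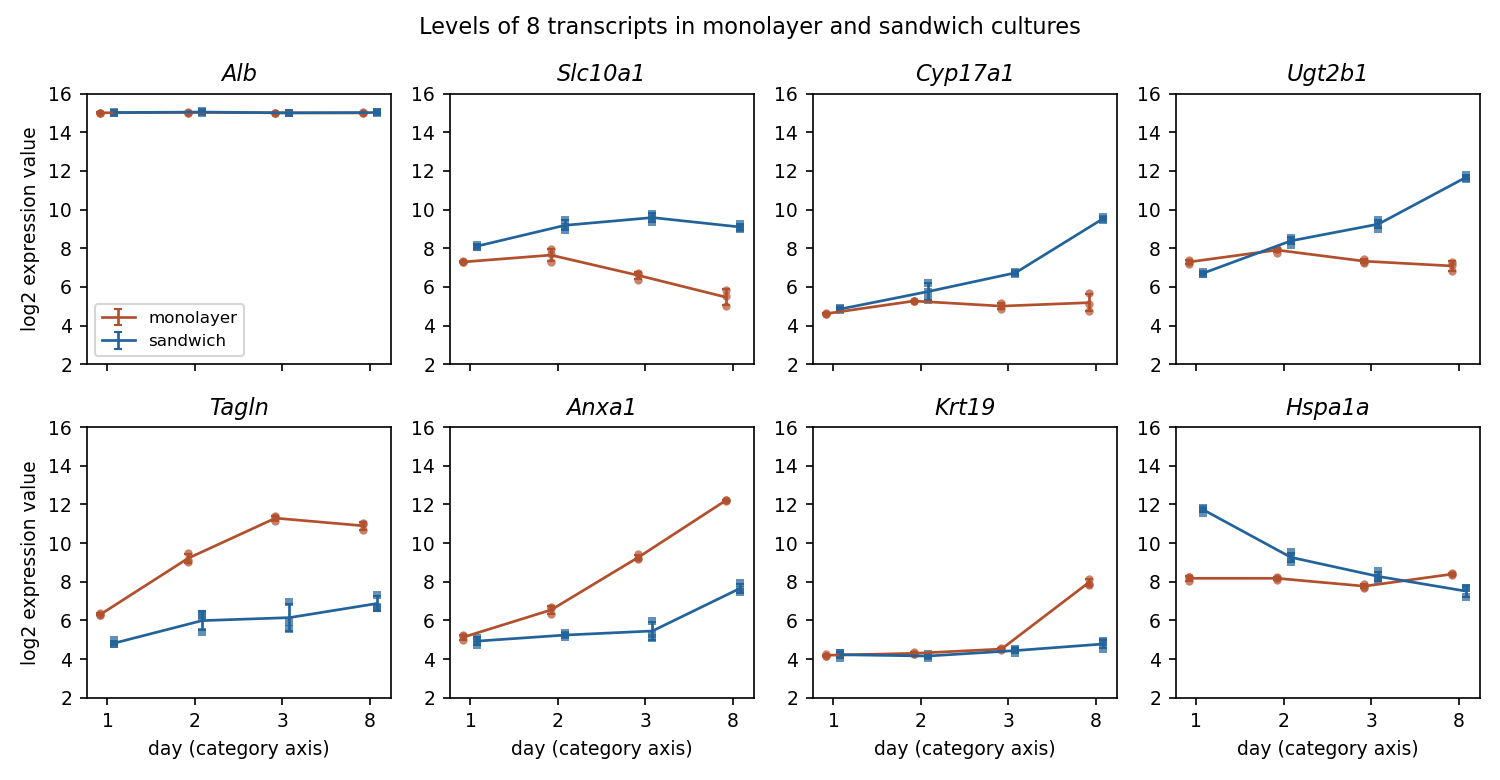
Log2 level of 8 transcripts (vertical axes) on each array at days 1, 2, 3 and 8 (horizontal axes), with points for arrays and lines through the group means of monolayer and sandwich. Ugt2b1 and Cyp17a1 stood higher in sandwich at day 8, Tagln, Anxa1 and Krt19 stood higher in monolayer at day 8, and Hspa1a was highest in sandwich at day 1.

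Urea cycle and amino acid genes at day 8 were higher in 39 of 40, lower in 0, and 1 did not pass, with 39 higher adjusted over the list alone (median 1.67, adjusted p = 1.52e-35, and 0.0059 with an estimated correlation). Got1 stood at 3.11 ± 0.10 and the methyltransferase Gnmt at 2.69 ± 0.11. Cholesterol synthesis was higher in 19 of 21, fatty acid synthesis in 17 of 19, gluconeogenesis in 12 of 16 and bile acid synthesis in 12 of 15, with none lower and medians of 1.45, 1.43, 1.37 and 0.77. Their adjusted p-values with an estimated correlation were 0.0139, 0.0141, 0.0059 and 0.0055. Examples were Insig1, a regulator of sterol synthesis, at 2.81 ± 0.13, the lipogenic gene Thrsp at 3.26 ± 0.14, the desaturase Scd at 3.07 ± 0.14 and the sterol hydroxylase Cyp8b1 at 2.94 ± 0.12. Fatty acid oxidation had 31 higher and 1 lower of 34 (median 0.84, adjusted p = 0.0097 with an estimated correlation), with Pdk4 at 3.84 ± 0.18 and Cyp4a3 at 2.68 ± 0.10. Phase I drug metabolism had 26 higher and 2 lower of 39 (median 0.65, adjusted p = 0.0079 with an estimated correlation), with the cytochrome Cyp3a23-3a1 at 3.44 ± 0.16 and, in the other direction, Aldh1a1 at -1.55 ± 0.09. Phase II had 23 higher and 6 lower of 39, transporters 19 and 2 of 30, and plasma proteins 24 and 1 of 29 (adjusted p = 0.0325, 0.0141 and 0.0235 with an estimated correlation). The glutathione transferase Gstp1 was among the lower ones at -2.21 ± 0.09, while the apolipoprotein Apoa4 stood at 3.03 ± 0.12.

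Actin cytoskeleton genes at day 8 were lower in 30 of 32 and higher in 0, with 32 lower adjusted over the list alone (median -0.88, adjusted p = 2.95e-16, and 0.0046 with an estimated correlation). Mesenchymal transition had 23 lower and 1 higher of 35 (median -0.68, adjusted p = 0.0038 with an estimated correlation), with the galectin Lgals3 at -2.69 ± 0.10 and the hyaluronan receptor Cd44 at -2.22 ± 0.11. Integrins had 22 lower and 1 higher of 36, cell cycle 26 and 0 of 44, and matrix proteases and inhibitors 13 and 1 of 30, with the gelatinase Mmp2 at -2.90 ± 0.14 (adjusted p = 0.0171, 0.0084 and 0.0308 with an estimated correlation). Cholangiocyte markers moved with them, at 6 lower and 1 higher of 12 (median -0.58, adjusted p = 1.09e-04, and 0.0059 with an estimated correlation), such as the bile duct keratins Krt19 at -3.19 ± 0.11 and Krt7 at -3.22 ± 0.15 and the secretin receptor Sctr at -1.26 ± 0.09. That call ended when the 40% of probe sets with the lowest means were left out. The junction list was not called (adjusted p = 0.739), with 10 higher and 11 lower of 34. In it the gap junction gene Gjb2 stood at 2.96 ± 0.11, while Ezr and Msn, which tie actin to the membrane, stood at -2.86 ± 0.09 and -2.99 ± 0.11.

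Glycolysis (adjusted p = 0.256) and oxidative stress (0.387) were not called at day 8. Of 26 called lists, 10 did not hold with an estimated correlation. Those higher in sandwich were coagulation and complement (23 of 29 higher, adjusted p = 0.0636 with an estimated correlation), acute phase (12 of 17, 0.0582), oxidative phosphorylation (29 of 45, 0.112), liver transcription factors (14 of 26, 0.0728), inflammation (8 of 30, 0.101), endoplasmic reticulum stress (13 of 27, 0.142) and immediate early genes (10 of 23, 0.115). Those lower were collagen and extracellular matrix (14 of 36 lower, 0.195), fetal and progenitor markers (6 of 17, 0.128) and heat shock (8 of 13, 0.195). The inflammation call also ended with the preset correlation without monolayer replicate 2 (adjusted p = 0.0626) or 3 (0.0543) or sandwich replicate 1 (0.0597) or 3 (0.0541) of day 8. Among markers of other liver cells, macrophage (3 higher and 3 lower, adjusted p = 0.587), stellate cell and fibroblast (0.988), endothelial (0.74), lymphocyte (0.596) and neutrophil and erythroid markers (0.504) were not called at day 8. The pericyte gene Rgs5 stood at 1.84 ± 0.11 and the fibrillar collagen Col3a1 at -0.88 ± 0.22.

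**Figure D3:**
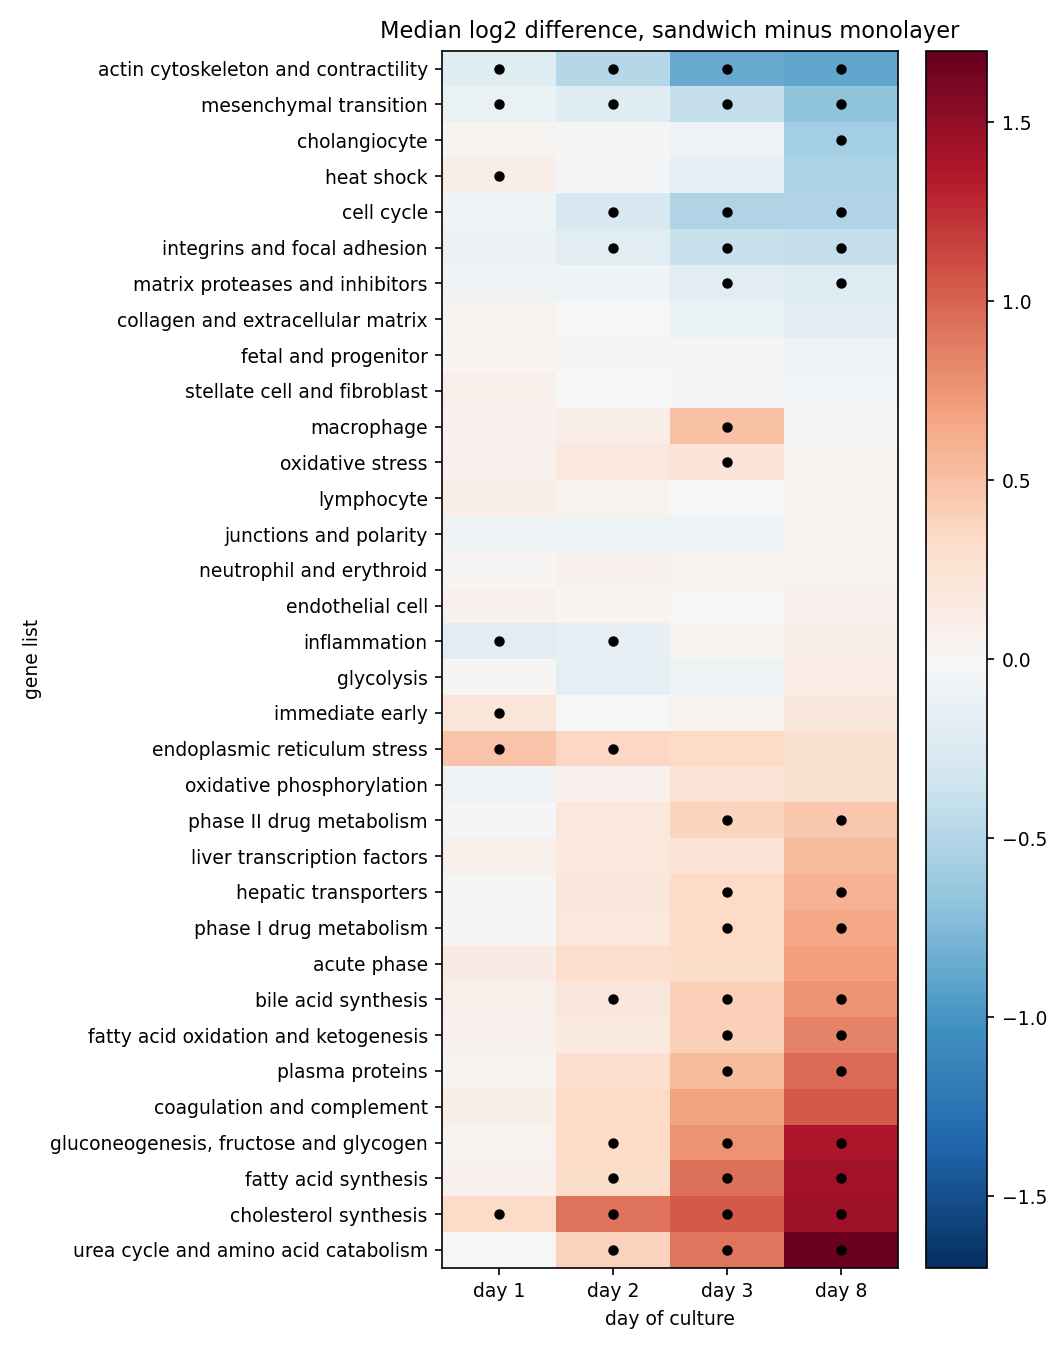
Median log2 difference, sandwich minus monolayer, of the measured members of each gene list (rows) at each day (columns), as colour, with dots on lists called with both the preset and an estimated correlation. Urea cycle and amino acid genes reached a median of 1.67 at day 8 and actin cytoskeleton genes -0.88.

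Several classical hepatocyte genes were followed whatever their values. For albumin, Alb, the probe set with the higher mean did not pass at any day, with log2 differences from -0.01 to 0.02 at a level of 15.0. The highest value of all arrays, 15.07, belongs to this same probe set, so whether the scale leaves room for a rise to show is unknown. The second Alb probe set, with a mean of 14.63, was higher in sandwich at day 8 by 0.21 ± 0.07 (adjusted p = 0.0214) and did not pass at the other days. Slc10a1 was higher in sandwich at all 4 days, by 0.82, 1.54, 2.99 and 3.63 (SE 0.17). Hnf4a, a liver transcription factor, was higher by 0.46 ± 0.10, 0.64 ± 0.10, 0.99 ± 0.10 and 0.54 ± 0.10, and its day 1 call ended without monolayer replicate 3 (adjusted p = 0.0915) or sandwich replicate 3 (0.0888) of that day. Another Hnf4a probe set was called at day 3 but not at days 1, 2 and 8 (adjusted p = 0.581, 0.0581 and 0.0885). A further one was called at days 2, 3 and 8 but not at day 1 (0.347). Cps1, the entry enzyme of the urea cycle, was higher by 0.79 ± 0.13 at day 3 and 2.06 ± 0.13 at day 8, and tyrosine aminotransferase, Tat, by 0.62 ± 0.12, 0.83 ± 0.12 and 2.15 ± 0.12 at days 2, 3 and 8. Abcb11, the bile salt export pump, was higher by 1.04 ± 0.16 at day 3 and 2.76 ± 0.16 at day 8. Cyp2e1 was higher by 2.12 ± 0.18 at day 8, and its difference of 0.41 at day 3 did not pass (adjusted p = 0.156). At day 8 transthyretin, Ttr, was higher by 0.26 ± 0.07, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 0.36 ± 0.11, a call that ended without monolayer replicate 1 of that day (adjusted p = 0.105). Cebpa was higher by 1.09 ± 0.24 at day 3, and its 0.53 at day 8 did not pass. Its other probe sets had adjusted p-values of 0.0030, 0.0238, 0.0544 and 0.0609 at day 3. Alpha-fetoprotein, Afp, was higher by 0.79 ± 0.10 at day 3 and 1.06 ± 0.10 at day 8. Ccnd1 was lower at all 4 days, from -1.05 ± 0.16 at day 1 to -2.14 ± 0.16 at day 8, and the proliferation marker Mki67 stood at -0.83 ± 0.10 and -0.72 ± 0.10 at days 3 and 8. Vimentin, Vim, stood at -1.61 ± 0.15 and -2.34 ± 0.15 at those days. Acta2 (from -0.61 to -0.04) and Col1a1 (from 0.07 to 0.24) were not called at any day.

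Some calls of these genes ended when 1 array was left out, several of them without any of most arrays, and leaving out an array also lowers the power. At day 2, Cps1 (0.56) was not called without sandwich replicate 1 (adjusted p = 0.0502), and Cebpa (1.03) not without monolayer replicate 3 (0.0723) or sandwich replicate 1 (0.0757). Another Cps1 probe set was called at day 2 with all arrays, at 0.69 ± 0.13 (adjusted p = 0.0015). No other probe set of Cebpa was called at day 2 with all arrays (adjusted p from 0.0850 to 0.236). Vim (-0.54) was not called without monolayer replicate 1 (0.111) or 2 (0.0832) or sandwich replicate 2 (0.128) or 3 (0.131) of day 2. Mki67 (-0.38) was not called without monolayer replicate 1 (0.137) or 2 (0.101) or sandwich replicate 1 (0.0552) or 2 (0.131). Afp (0.37) was not called without any of monolayer replicates 1 (0.0985) and 3 (0.193) and sandwich replicates 1 (0.136), 2 (0.0752) and 3 (0.0697). At day 3, Ttr (0.24) was not called without monolayer replicate 1 (0.0538), 2 (0.0819) or 3 (0.0679) or sandwich replicate 1 (0.106).

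Averaged over the 4 days, sandwich cells held more of the lipid, amino acid and plasma protein transcripts and less of the contractile and proliferative ones. Each of the 32 actin cytoskeleton genes was lower (median -0.56, adjusted p = 9.34e-24, and 0.0021 with an estimated correlation), and cell cycle genes were lower in 34 of 44 and higher in 0 (adjusted p = 0.0047 with an estimated correlation). Endoplasmic reticulum stress genes were higher in 20 of 27, plasma protein genes in 25 of 29 and fatty acid synthesis genes in 18 of 19, with 0, 0 and 0 lower (adjusted p = 0.0148, 0.0239 and 0.0158 with an estimated correlation). Of 25 called lists 17 held in that way, and the other 8 had adjusted p-values from 0.0544 to 0.326 with an estimated correlation. In all, 9141 probe sets differed in the mean of the 4 days, 4143 higher and 4998 lower in sandwich, 338 of them by at least 2-fold.

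Within monolayer, comparison with day 1 showed how the control culture changed: fatty acid synthesis, gluconeogenesis and oxidative stress genes fell, and cytoskeletal, mesenchymal, matrix and progenitor genes rose. Vim, an intermediate filament protein of mesenchymal cells, stood at 12.86 ± 0.22 against 6.12 ± 0.18 at day 8 and day 1 (mean ± SD, n = 3 each), a 107-fold rise (adjusted p = 2.37e-20). Map2, a microtubule-associated protein, stood at 10.93 ± 0.51 against 3.26 ± 0.10 (adjusted p = 2.76e-19), and as its day 1 level is near the lowest value of the table, 2.61, no fold is given. Anxa1 rose by 7.07 ± 0.16 on the log2 scale (adjusted p = 2.37e-20), while the carboxylesterase Ces1c fell 30.9-fold (adjusted p = 2.37e-20). Cd24, Rgs2, Acta1, Igfbp7, Plscr2, Tagln and Cav1 were the other large rises, from 4.43 to 6.17 on the log2 scale. Rup2, G0s2, Apoa2, Serpina6, Cxcl9, Serpina3l, Serpina3c, Slc17a1 and Slc17a3 were the other large falls, from -4.98 to -3.63.

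Mesenchymal transition genes in monolayer rose in 25 of 35 and fell in 3 by day 8 (median 0.96, adjusted p = 8.21e-14, and 0.0036 with an estimated correlation). Actin cytoskeleton genes rose in 22 of 32 and fell in 0, collagen and matrix genes in 23 of 36 and 1, and cell cycle genes in 18 of 44 and 1 (adjusted p = 0.0084, 0.0244 and 0.0348 with an estimated correlation). The basement membrane collagen Col4a1 rose by 3.88 ± 0.18 and the cyclin Ccnd2 by 4.07 ± 0.20. Fetal and progenitor markers rose in 10 of 17 and fell in 1, cholangiocyte markers in 7 of 12 and 0, matrix proteases in 14 of 30 and 1, and integrins in 16 of 36 and 3. Their adjusted p-values with an estimated correlation were 0.0109, 0.0025, 0.0144 and 0.03. Fatty acid synthesis fell in 15 of 19 and rose in 0, gluconeogenesis in 12 of 16 and 1, and oxidative stress in 18 of 23 and 0, with the aldo-keto reductase Akr1b8 at -2.70 ± 0.10 (adjusted p = 0.0422, 0.0336 and 0.006 with an estimated correlation). The other 11 of 22 called lists did not hold, among them falls of the urea cycle list (24 of 40), coagulation (21 of 29) and cholesterol synthesis (16 of 21), at adjusted p = 0.147, 0.197 and 0.0899 with an estimated correlation. In total 1556, 6161 and 9555 probe sets differed from day 1 at days 2, 3 and 8. The last divided into 4661 higher and 4894 lower, and into 3752 and 6154 when each array was centred on its median. The day 2 count fell to 982 without monolayer day 1 replicate 1, 1002 without its replicate 2 and 990 without monolayer day 2 replicate 3, and rose to 3578 with array weights.

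Sandwich cells changed over the same days too, with amino acid and fatty acid oxidation genes rising beside mesenchymal and bile duct-type ones, and stress genes falling. The desaturase Scd2 stood at 11.08 ± 0.29 against 4.67 ± 0.34 at day 8 and day 1 (mean ± SD, n = 3 each, adjusted p = 4.56e-16). The neuropeptide gene Npy rose 61.3-fold (adjusted p = 4.04e-18), Ugt2b1 30.9-fold (adjusted p = 2.69e-19) and Vim 23.9-fold (adjusted p = 4.15e-17). Ces1c fell 37.7-fold (adjusted p = 2.53e-20) and Hspa1a 18.4-fold (adjusted p = 3.13e-17). Cyp17a1, Clec14a, Slc25a4, Pglyrp1, Map2 and Ccn2 were the other large rises, from 3.98 to 4.67 on the log2 scale. Rup2, Cxcl9, Serpina6, Rsad2, Serpina3c, Ptgr1, Mat2a and Slc17a3 were the other large falls, from -4.84 to -2.69.

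Urea cycle and amino acid genes in sandwich rose in 29 of 40 and fell in 3 (median 1.13, adjusted p = 8.11e-17, and 0.03 with an estimated correlation). Fatty acid oxidation rose in 25 of 34 and fell in 3, with the carnitine transferase Cpt1a at 2.68 ± 0.10, and bile acid synthesis rose in 8 of 15 and fell in 2 (adjusted p = 0.0327 and 0.032 with an estimated correlation). Oxidative stress genes fell in 15 of 23 and rose in 0, and endoplasmic reticulum stress genes fell in 18 of 27 and rose in 3, with Creld2 at -2.12 ± 0.12 (adjusted p = 0.0055 and 0.0463 with an estimated correlation). Mesenchymal genes rose in 15 of 35 and fell in 6, fetal and progenitor markers in 9 of 17 and 0, cholangiocyte markers in 6 of 12 and 0, and inflammation genes in 12 of 30 and 3. Their adjusted p-values with an estimated correlation were 0.0425, 0.0276, 0.0126 and 0.0276. The other 12 of 21 called lists had adjusted p-values from 0.0787 to 0.617 with an estimated correlation. All these p-values were adjusted over the 8 comparisons together. Adjusted within this comparison alone, only 2 lists were called with an estimated correlation, so most of these list calls rest on the joint adjustment. Probe sets that differed from day 1 numbered 1802, 4601 and 7694 at days 2, 3 and 8, the last with 3589 higher and 4105 lower, and the day 2 count was 2722 with array weights. At day 8, 1895 probe sets had risen and 2390 had fallen in both cultures, against 539 and 647 for independent lists. Another 418 fell in monolayer and rose in sandwich, and 171 did the reverse, against 566 and 616. All time comparisons of a culture share its day 1 arrays.

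The change from day 1 to day 8 differed between the cultures in liver metabolism, cytoskeleton and inflammation. Ugt2b1 changed more in sandwich by 5.16 ± 0.17 on the log2 scale (adjusted p = 6.71e-16) and Cyp17a1 by 4.10 ± 0.24 (adjusted p = 5.95e-12), while Cd24 differed by -4.74 ± 0.30 (adjusted p = 2.78e-11) and Hspa1a by -4.42 ± 0.19 (adjusted p = 4.40e-14). Urea cycle and amino acid genes changed more upwards in sandwich in 39 of 40 and less in 0 (median 1.49, adjusted p = 5.32e-40, and 0.0047 with an estimated correlation). Inflammation genes did so in 12 of 30, with 2 in the opposite direction (median 0.43, adjusted p = 0.0059 with an estimated correlation). The chemokine Cxcl2, for example, was lower in sandwich at day 1 at -0.76 and higher at day 8 at 1.48. Actin cytoskeleton genes differed downwards in 20 of 32 and upwards in 0 (median -0.57, adjusted p = 0.0124 with an estimated correlation). Heat shock genes differed downwards in 7 of 13 and upwards in 2, and their call did not hold (adjusted p = 0.0643 with an estimated correlation). By this contrast 4852 probe sets were called, 2422 upwards and 2430 downwards, and by the interaction over all 4 days 4618. Of 24 called lists 16 held with an estimated correlation.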

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

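The results here are those where the culture difference itself changed between days, by a test of that change. The counts of other splits of the arrays were planned before the data were examined, and the tests on heat shock genes, on other cell types and on RNA quality, range and normalization were chosen after the results were seen.

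Between day 1 and day 8 the culture difference grew upwards most in Ugt2b1 (5.16 on the log2 scale), Cyp17a1 (4.10), Clec14a (3.94), Apoa2 (3.94), Rbp7 (3.69), Ftcd (3.53), Urad (3.43) and Scd2 (3.37). It moved downwards most in Cd24 (-4.74), Hspa1a (-4.42), Anxa1 (-4.35), Car3 (-4.23), Plscr2 (-4.08), Cpe (-3.98), Acta1 (-3.67) and Map2 (-3.64). Each of these 16 genes was called with an adjusted p under 0.05, with 3 arrays in each of the 4 groups.

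Among the lists, the medians of this change were 1.49 for urea cycle and amino acid catabolism, 1.41 for fatty acid synthesis, 1.20 for cholesterol synthesis, 1.17 for gluconeogenesis, 0.85 for phase I drug metabolism, 0.78 for plasma proteins, 0.72 for fatty acid oxidation, 0.68 for bile acid synthesis, 0.50 for transporters, 0.43 for phase II drug metabolism and 0.43 for inflammation. Downwards they were -0.57 for actin cytoskeleton, -0.42 for mesenchymal transition, -0.39 for cell cycle, -0.32 for cholangiocyte markers and -0.17 for matrix proteases. These 16 lists held with an estimated correlation, and the call of cholangiocyte markers ended without the 40% of probe sets with the lowest means. The calls of 8 lists did not hold. Their medians were 0.95 for coagulation and complement (adjusted p = 0.0901 with an estimated correlation), 0.43 for acute phase (0.116), 0.36 for oxidative phosphorylation (0.0643), 0.32 for liver transcription factors (0.119), -0.47 for heat shock (0.0643), -0.29 for collagen and extracellular matrix (0.117), -0.25 for integrins (0.0567) and -0.0957 for fetal and progenitor markers (0.0584).

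In all, 4852 probe sets were called for the change between day 1 and day 8 and 4618 for the interaction over the 4 days. Of 100 splits that exchanged culture labels within days, 10 gave as many as 4852 probe sets (highest other 6210), so that chance cannot be excluded for that count by this test. The 9 others all kept the day 8 groups whole, 13 such splits having been drawn, and with the day 8 groups broken up the highest count was 15. The large counts therefore followed a structure of the samples, the difference between the cultures at day 8. For the interaction, 3 of 100 splits gave as many as 4618 (highest other 5544, and 11 with the day 8 groups broken up). The 2 others kept the day 8 groups whole, 10 such splits having been drawn. Exchanging labels removes the culture difference as a whole, so this rank does not test the interaction by itself. For the mean of the 4 days 1 of 100 gave as many as 9141 (highest other 5686), so that chance labels are unlikely to give that count.

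For each pair of groups, 3 arrays against 3 make only 10 splits, too few for a share under 0.05. The real split gave the highest count in each, 1 of 10. The real counts at days 1, 2, 3 and 8 were 552, 1809, 5133 and 8543, against at most 0, 0, 1 and 1 in the other splits. Against day 1 they were 1556, 6161 and 9555 in monolayer (at most 0, 0 and 1) and 1802, 4601 and 7694 in sandwich (at most 2, 1 and 1). The lists behaved differently. With the preset correlation, 6 of 100 splits called as many lists as the 25 for the mean of the 4 days (highest other 25). For the change between day 1 and day 8, 16 of 100 called as many as its 24 (highest other 26). Of the other splits this large, 4 of 5 for the mean and 12 of 15 for the change kept the day 8 groups whole. Those splits still held the real day 8 difference. With the day 8 groups broken up the highest numbers were 25 and 24, so that chance cannot be excluded for those numbers of lists. At days 1, 2, 3 and 8 the real splits called 18, 24, 23 and 26 lists, reached by 1, 3, 3 and 1 of 10 splits (highest others 12, 25, 24 and 24), and day 8 against day 1 called 22 in monolayer (3 of 10, highest other 27) and 21 in sandwich (1 of 10, highest other 19). With an estimated correlation, adjusted within each comparison, 1 of 100 splits reached the 19 lists of the mean (highest other 11). Chance labels are thus unlikely to give that number. For the change, 2 of 100 reached its 20 lists (highest other 20), but exchanging labels removes the culture difference as a whole. That rank does not test the change by itself. At days 1, 2, 3 and 8 and for monolayer and sandwich against day 1 those numbers were 5, 11, 20, 17, 11 and 2, each reached by 1 of 10 splits with 0 lists in every other split.

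Heat shock transcripts were higher in sandwich at day 1 only in part of the list: Hspa1a, Hspb1 and Hsph1 were called. The smallest log2 difference of these 3 genes over the fits without each of the 6 arrays was 0.47. Of 366 genes called at day 1, 365 had all 3 arrays of one culture above the 3 of the other. Leaving out 1 array cannot turn the sign of such a gene, so the sign alone tests nothing. The size of the difference says more. On the single day 1 arrays, Hspa1a ran from 11.58 to 11.80 in sandwich and from 8.04 to 8.27 in monolayer. As at least 0.47 remained in every fit, the values argue against a single array as the whole cause for these 3 genes. From day 1 to day 8 the culture difference in these genes changed by a median of -2.59 on the log2 scale (median SE 0.16), and Hspb1 was lower in sandwich at -1.17 ± 0.12. A candidate explanation is a passing response to handling when the second layer was laid on, but deposition is part of the sandwich condition, so that handling and culture form cannot be told apart for these genes. The sandwich environment itself stays open as the biological alternative.

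Actin and mesenchymal transcripts were higher in monolayer from day 1 on. More stellate cells or fibroblasts in monolayer at day 3 stay open: their 19 measured markers had a median difference of -0.0383 with a spread of 0.18, against -0.71 for the 66 genes of the actin and mesenchymal lists, but the median level of these markers in monolayer was only 5.21, below the 5.62 of all probe sets, and markers near the floor decide nothing (the collagens Col1a2 and Col3a1 stood at 4.76 and 5.11). At day 8 such cells stay open for the pattern as a whole: the 5 markers of the list that had risen in both cultures (Reln, Col1a1, Col1a2, Col3a1 and Mgp) had a median difference of -0.55 with a spread of 0.52, between -0.90 and 0.11, which reaches the median of -0.73 of the 66 genes though not the -4.02 of Tagln. More cholangiocytes at day 8 stay open as well, since their 12 measured markers had a median of -0.58 with a spread of 1.05, and 5 of the 12 are also on the fetal and progenitor list. A change of state in the hepatocytes of the monolayer is the biological explanation that the design offers, and it was not tested.

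The breadth of the culture difference at day 8, 8543 probe sets, is unlikely to come from the technical measures that could be tested. With the 3' minus 5' difference of beta-actin as a covariate 7734 probe sets were called, with the interquartile range of each array 9394, and under the less favourable of quantile normalization and median centring 8501. Each lies within 1.5 times the count, so that neither covariate is the whole cause. The deposited values were already normalized between arrays, so normalizing them again cannot test the normalization used by the authors. The labels name no batches of culture, labelling or hybridization, so none was weighed apart from the replicate number as a block, given below. The culture form is the biological explanation of the design.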

How the results depend on the processing

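The alternatives were planned before the data were examined, except leaving out all arrays numbered 1 and both covariates, which were chosen after the data were seen. No list or named gene that was called turned its direction under the alternatives run for it, but the balance of higher and lower probe sets within some counts did. The lists were not run with either covariate, with the variance prior with a trend, or on only the groups compared. They were also not run without all arrays numbered 1. With the interquartile range of the arrays as a covariate 351 were higher and 348 lower at day 1, against 178 and 374. Quantile normalization gave 921 higher and 828 lower for monolayer at day 2, against 755 and 801, and median centring gave 2119 and 2048 for sandwich at day 3, against 2296 and 2305, and 2685 and 1843 for the change between day 1 and day 8, against 2422 and 2430. With at least 2-fold asked for, 704 were higher and 664 lower at day 8, against 3695 and 4848. Without sandwich replicate 3 of day 3, 2330 were higher and 2311 lower at that day, against 2390 and 2743. Counts within each culture and of the change, which lay near even, turned under further alternatives as well. Quantile normalization, median centring, the variance prior with a trend, the replicate number as a block, leaving out the 40% of probe sets with the lowest means, leaving out possibly cross-hybridizing probe sets, fitting only the groups compared, and both covariates kept every count of probe sets within 1.5 times. No scaling moved the median of all probe sets by more than 0.07 on the log2 scale. The replicate block gave 793, 2261, 5898 and 9472 probe sets at days 1, 2, 3 and 8. The labels do not say that equal replicate numbers belong together across groups, and the block ended no list or gene call, adding 2 list calls and 23 of named genes. As a hint from the data, the median correlation of residuals was 0.20 for 84 pairs of arrays with the same number, from -0.43 to 0.53, and -0.13 for pairs with different numbers, and 15 of 24 arrays correlated best with arrays of their own number. Between arrays numbered 1 every correlation was positive, from 0.06 to 0.50, while those between arrays numbered 2 or 3 went both ways. The arrays numbered 1 thus share a structure whose source the labels do not name.

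With 1 probe set per gene the counts were 5489 at day 8, 5712 for the mean of the days, 4044 and 5803 for monolayer at days 3 and 8 and 4812 for sandwich at day 8, because fewer probe sets were tested. Array weights gave 933 at day 1, 3688 at day 2, 3578 for monolayer at day 2 and 2722 for sandwich at day 2, and the cause was not tested. A stricter adjusted p under 0.01 gave 276 and 1092 at days 1 and 2, 806 for monolayer at day 2, and 1136 and 2953 for sandwich at days 2 and 3. Asking also for 2-fold gave 54, 208, 727 and 1368 at days 1, 2, 3 and 8, 338 for the mean, 120, 587 and 1668 for monolayer, 194, 479 and 1066 for sandwich, 1236 for the change between day 1 and day 8 and 1348 for the culture by day interaction. Leaving out all arrays numbered 1, which leaves 2 per group, gave 159, 846 and 3281 at days 1, 2 and 3, 582 and 3946 for monolayer and 782 and 2569 for sandwich at days 2 and 3, 2936 for the change and 2414 for the interaction. Leaving out 1 array at a time gave 322 to 465 at day 1 and 982 to 1428 for monolayer at day 2, and elsewhere stayed within 1.5 times. Fewer arrays per group lower the power in both cases.

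With an estimated correlation the number of called lists moved from 18 to 7 at day 1, from 24 to 11 at day 2, from 26 to 16 at day 8, from 22 to 11 for monolayer and from 21 to 9 for sandwich between day 1 and day 8. The estimated correlation was above the preset 0.01 in 33 of 34 lists (median 0.116, from -0.0012 to 0.515), and the test with an estimate also has fewer degrees of freedom. How much of the loss each of the 2 accounts for was not tested. Of 272 list results, 79 lost their call in that way and 0 gained one, while fry ended 8 calls and added 30. Leaving out the 40% of probe sets with the lowest means ended 11 list calls and added 3. Among 1188 values of named genes, leaving out all arrays numbered 1 ended 75 calls and added 6, the 3' minus 5' covariate ended 21 and added 7, fitting only the groups compared ended 24 and added 7, and median centring ended 10 and added 6. The table has no detection calls, so how far low signals stand above background is unknown.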

Other observations

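In this part the added lists of YAP target, hypoxia-induced and interferon-induced genes, their tests, and the genes Bhlhe41, Noct, Per1, Nr1d1, Clock, Ankrd1, Amotl2 and Isg15 were chosen after the data were seen. The endothelial, macrophage and acute phase lists were fixed before, and the other genes follow the rule for named genes in at least 1 comparison, though not in each one given here.

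The receptor genes Cd14 and Fcgr2b were higher in sandwich as single genes. Cd14, the lipopolysaccharide co-receptor, was higher in sandwich at days 1, 2, 3 and 8 by 0.54 ± 0.08, 0.61 ± 0.08, 0.84 ± 0.08 and 0.98 ± 0.08 (log2 difference ± SE, n = 3 each), and Fcgr2b, an inhibitory immunoglobulin receptor, by 0.98 ± 0.18, 1.85 ± 0.18 and 2.38 ± 0.18 at days 2, 3 and 8. The endothelial list to which Fcgr2b belongs was not called at any day, with 1 higher and 1 lower of 17 at day 3 (adjusted p = 0.975). The macrophage list, which holds Cd14, was called at day 3 but not at the other 3 days, and had 2 higher and 1 lower of 20 at day 1 (adjusted p = 0.0738), 1 and 1 at day 2 (0.102), 12 and 1 at day 3 (1.54e-04), and 3 and 3 at day 8 (0.587). Cd14 is also on the acute phase list. The small heat shock protein Cryab was lower at days 2, 3 and 8 at -1.16 ± 0.10, -1.69 ± 0.10 and -1.28 ± 0.10, while Nfkbiz, a nuclear regulator of inflammatory genes, was higher by 1.08 ± 0.13, 1.48 ± 0.13 and 1.78 ± 0.13.

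Single genes with large or opposed differences were also looked at one by one. Bhlhe41, a transcriptional repressor, stood at -0.94 ± 0.15, -2.78 ± 0.15 and -2.61 ± 0.15 in sandwich minus monolayer at days 2, 3 and 8. Noct, a deadenylase-family gene, stood at -0.88 ± 0.11, -1.66 ± 0.11, -1.95 ± 0.11 and -0.78 ± 0.11 at days 1, 2, 3 and 8. The transcription factor gene Dbp was higher by 1.39 ± 0.11 at day 8. Per1, Nr1d1 and Clock were not called at any of the 4 days, and no circadian list was tested. Npy was lower in sandwich at day 3 at -2.10 ± 0.17 and higher at day 8 by 1.72 ± 0.17.

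Lower YAP-dependent transcription in sandwich is a hypothesis raised by the actin and Ccn2 values. Of 22 target genes written down for the test 21 were measured, 5 of them also on the fixed lists. At days 1, 2, 3 and 8 they were lower in 5, 8, 12 and 15 and higher in 0, 0, 1 and 0, with medians of -0.11, -0.33, -0.40 and -0.53 (adjusted p = 0.0270, 6.55e-04, 6.87e-04 and 6.87e-04 with an estimated correlation, 12 tests adjusted together). Ankrd1, a target in many cell types, stood at -3.12 ± 0.21 and Amotl2 at -0.90 ± 0.10 at day 3. Without Ccn2 and the other 4 genes on the fixed lists, the remaining 16 were lower in 4, 7, 9 and 12 and higher in 0 on each day, with medians of -0.18, -0.42, -0.51 and -0.57 (adjusted p = 0.0175, 6.11e-04, 6.11e-04 and 7.61e-04 with an estimated correlation, 8 tests adjusted together). The test uses the arrays that raised the hypothesis. The values are consistent with it, but transcripts alone do not show the activity of YAP.

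Less oxygen under the second gel layer was a further hypothesis. The highest of the 4 medians of 25 hypoxia-induced genes, 11 of them also on the fixed lists, was 0.14, at day 8, with 9 higher and 6 lower (adjusted p = 0.608 with an estimated correlation). At day 2 the list was lower in sandwich, with a median of -0.20 and 8 lower and 0 higher (adjusted p = 0.0302 with an estimated correlation). At day 1 it had 0 higher and 0 lower and a median of 0.01 (adjusted p = 0.717 with an estimated correlation). At day 3 it had 2 higher and 6 lower and a median of -0.12 (0.365). No rise of the list was called on any day with an estimated correlation. These values do not decide the question, since members went both ways at days 3 and 8.

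An interferon response in sandwich at day 1 was tested because Rsad2 was among the largest rises. Of 26 genes 22 were measured, 1 of them also on the fixed lists, and 4 were higher and 2 lower, with a median of 0.15 (adjusted p = 0.0406 with an estimated correlation). Rsad2 was higher by 1.29 ± 0.22 and Isg15 by 0.73 ± 0.14, while Cxcl10 stood at -1.04 ± 0.15. At days 2, 3 and 8 the list was not called (adjusted p = 0.975, 0.717 and 0.717 with an estimated correlation). Without Rsad2, the gene that prompted the test, the day 1 list had 3 higher and 2 lower of 21 and a median of 0.14, and it was not called (adjusted p = 0.0857 with an estimated correlation, 8 tests adjusted together). The unadjusted p was 0.0203 with Rsad2 and 0.0536 without it, so that the call was lost before any adjustment, while with the preset correlation the list without Rsad2 was still called (adjusted p = 0.0035). These values leave an interferon response open.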
